A study of Saccharomyces cerevisiae and Caenorhabditis elegans with 98 samples.

How the data were processed

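Counts per gene as deposited by the authors were used, and no reads were aligned here. Per the labels' protocols, yeast of the BY4741 background were grown in YPD, or in synthetic medium without leucine for strains with plasmids, and collected at an OD600 of 0.4. Diamide was given at 1.5 mM for 30 min and rapamycin at 12.5 nM for 30 min. Cultures received cycloheximide for 1 min and the lysis buffer held 100 µg/ml of it, except in the libraries made without the drug. Lysates were digested with RNase I, and monosome footprints of 28 to 32 nt were cloned, while poly(A) mRNA was cloned as fragments of 50 to 80 nt. Nematodes were N2, tut-1(tm1297) and tut-1(tm1297) elpc-1(tm2149), with footprints from animals of the fourth larval stage and poly(A) mRNA from adults of day 1. Per the submitters' processing notes, bases were called with CASAVA 1.8 and reads aligned with Bowtie 1.0.0 to sacCer3. The counting program and the annotation are not given in the sources used here. The nematode samples name the yeast build too, so no nematode coordinates were used.

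Of 98 libraries in the labels, 80 were used in 28 groups, and 18 were not analysed here (strains that lack hbs1 or dom34, paromomycin, and the wild type with tEKQ). Replicates are biological per the text of the series, 3 per yeast group and 2 per nematode group. One label tags the wild-type libraries made without cycloheximide as ncs2Δ. Their titles were followed, as NCS2 had 300 to 360 reads in them. Totals ranged from 5935901 to 16056767 counts for yeast footprints, 4888064 to 16380240 for yeast mRNA, 3290767 to 16919649 for plasmid strains, 1632401 to 12876047 for nematode footprints and 31664260 to 43447181 for nematode mRNA. Replicate 2 of each nematode footprint group was the shallow one. The mRNA table lists 27 genes with missing values in some libraries, and each was left out of the fits that used those libraries. Names matched the reference for 5790 of 5794 yeast and 18193 of 18660 nematode genes, and coding sequences for 5770 of 5794 yeast genes. In the R64 reference NCS2 lies on chromosome XIV at 401040 to 402521 and ELP6 on XIII at 898405 to 899226, each with 1 coding exon.

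Before the data were examined, the groups, 43 comparisons, the test and its alternatives, and the gene lists were fixed. Of the planned comparisons 32 were run and 11 are not analysed here. A further 2 comparisons, of each mutant with tEKQ against the wild type with the empty plasmid, were added after the counts had been seen. Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after TMM scaling and filterByExpr, with 1 fit per family of libraries. A gene counted as higher or lower at a Benjamini-Hochberg adjusted p under 0.05, without a fold threshold. Translational efficiency and the interactions were tested as differences of differences in the same model. The common dispersion ranged from 0.00282 (footprints in YPD) to 0.0894 (nematode mRNA). Gene lists were tested with camera of limma 3.58.1, at its preset correlation of 0.01 and with an estimated correlation, and with fry. A list member was also called after adjustment over the list alone.

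The lists covered Gcn4 targets, cytosolic chaperones, endoplasmic reticulum chaperones, the proteasome, ribosomal proteins, ribosome biogenesis, Msn2 and Msn4 stress genes, Yap1 oxidative stress genes, sulfur and methionine genes, the iron regulon, glycolysis, respiration, the uridine 34 pathway, ribosome rescue, a-cell and α-cell genes, nitrogen catabolite repression and retrograde genes. The nematode lists covered cytosolic heat shock, organelle chaperones, collagens, major sperm protein, yolk, oocyte and eggshell, ribosomal proteins, lysozymes and lectins, oxidative detoxification and the uridine 34 pathway. All were drawn up from general knowledge of the genes.

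Genes were named by a rule, the 10 largest rises and 10 largest falls for the double deletion, for diamide and rapamycin footprints of the wild type, for elp6Δ with the empty plasmid and for the nematodes, and 4 of each elsewhere. They had to pass the test, reach a mean of 10 CPM and, for comparisons of 2 groups, show no overlap between the groups. Selection markers, transposons and dubious reading frames were left out of this rule, and deleted genes were always given. Of the genes chosen by the rule 1 is not reported here. Genes at 0 in a whole group are given as levels with a floor of 3 counts, which covers counting error only. Genes that share at least 20% of their 28-base words with other genes are named with that share and are uncertain. For AAD6 and for the nematode genes this share was not computed, so these genes are uncertain too. Spearman correlations with codon content used 100000 permutations.

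Alternatives were RLE scaling, no filter, the replicate number as a block, DESeq2 1.42.0, a fit of the contrast groups only, leaving out each library in turn, and for lists the estimated correlation. A count was taken to have changed when it moved by more than 1.5-fold. When a nematode library was left out, the group with a single library was assumed to vary like the other group. The replicate numbers were checked for pairing. In mRNA of the double deletion and wild type the residuals of equal numbers correlated at 0.164 to 0.409, so numbers may pair those samples. In nematode mRNA they correlated at 0.115, and elsewhere the numbers gave no clear pairing. The test was tested on simulated data with seeded changes. It recovered 64.0% of 1.25-fold and 98.0% of 2-fold changes for ncs2Δ footprints, 20.0% and 90.0% for ncs2Δ mRNA, 10.0% and 80.0% for ncs2Δ efficiency, and 0% of 2-fold but 66.0% of 4-fold changes for nematode footprints. False calls made up 1.78% to 11.1%, above the nominal share for ncs2Δ efficiency (10.8%), diamide footprints (9.23%), rapamycin mRNA (7.52%), ncs2Δ mRNA (5.33%) and the nematodes (10.8% and 11.1%). Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for codon counts, tables and figures.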

Results

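Yeast that lacked NCS2, ELP6 or both genes, and nematodes with mutations of tut-1, were compared with their wild types by counts of ribosome footprints and of mRNA fragments. NCS2 and tut-1 encode enzymes that thiolate uridine 34 of the tRNAs for lysine, glutamine and glutamate, and ELP6 encodes a subunit of the Elongator complex, which adds the carboxymethyl group to the same uridine. Yeast groups held 3 libraries and nematode groups held 2. Each deleted yeast gene was nearly without reads in its strain. NCS2 had 0 to 3 footprint reads per ncs2Δ library in rich medium (YPD) and 221 to 424 in the wild type, ELP6 had 0 to 3 in elp6Δ and 320 to 500 in the wild type, and in ncs2Δ elp6Δ the highest count of either gene was 1. MET17, which encodes O-acetylhomoserine sulfhydrylase and overlaps YLR302C on the other strand, had 3759 to 5138 footprint reads per ncs2Δ elp6Δ library and at most 15 reads in any library of the other strains. The double deletion thus differed from its wild type at this marker of methionine synthesis as well as at the deleted genes.

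**Figure D1:**
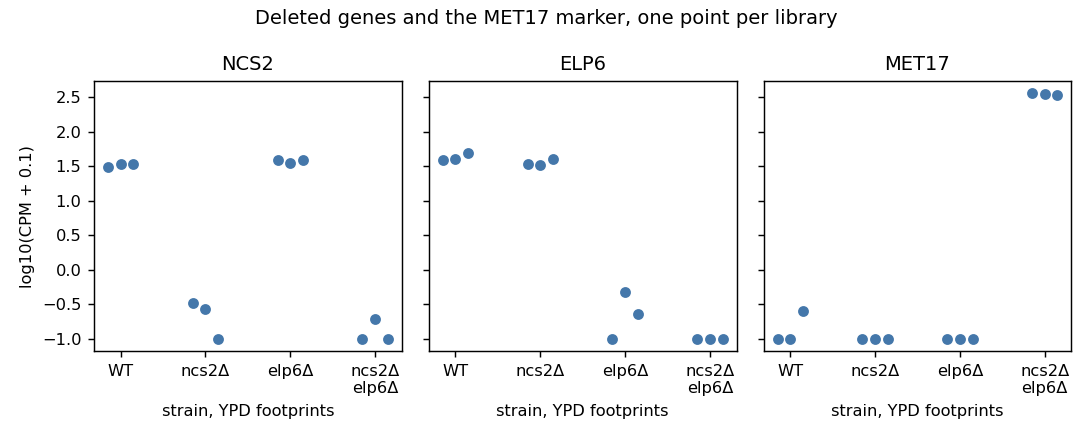
Footprints of NCS2, ELP6 and MET17 in YPD, as log10 of counts per 1e6 reads (CPM) plus 0.1, with one point per library of the wild type, ncs2Δ, elp6Δ and ncs2Δ elp6Δ. MET17 was high only in the ncs2Δ elp6Δ libraries.

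Loss of NCS2 raised footprints of proteasome and general stress genes, and single genes changed further. SER3, which encodes the first enzyme of serine synthesis, rose (log2 1.71 ± 0.11, adjusted p = 8.92e-10, 3 libraries against 3, ± giving the standard error). So did the membrane stress protein gene HSP12 (log2 1.55 ± 0.20, adjusted p = 6.56e-06) and the export pump gene ATR1 (log2 1.52 ± 0.12, adjusted p = 8.26e-09). The secreted acid phosphatase gene PHO5, which shares 21.5% of its 28-base words with other genes, fell (log2 -3.40 ± 0.19, adjusted p = 5.94e-11), with the mannoprotein gene TIR1 (log2 -2.16 ± 0.08), the phosphate transport regulator gene SPL2 (log2 -1.66 ± 0.20) and the ferric reductase gene FRE4 (log2 -1.60 ± 0.15). GCN4, which encodes the activator of amino acid synthesis, rose (log2 1.36, adjusted p = 3.01e-13).

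Of 32 proteasome genes, 24 rose and 2 fell in ncs2Δ (26 and 2 adjusted over the list alone), with a median log2 of 0.37, and PRE3 (log2 0.79) and RPN11 (log2 0.61) among the risers (camera adjusted p = 7.89e-19, adjusted p = 0.00895 with an estimated correlation). Of 25 general stress genes of the Msn2 and Msn4 factors, 14 rose and 1 fell (15 and 1 adjusted over the list alone), GAD1 (log2 1.06) and NTH1 (log2 0.58) among the risers (camera adjusted p = 1.70e-07, adjusted p = 0.00811 with an estimated correlation). Of 137 ribosomal protein genes, 2 rose and 70 fell (2 and 73 adjusted over the list alone), with a median log2 of -0.16 and the largest call at RPS9A (log2 -1.20) (camera adjusted p = 8.34e-10, adjusted p = 0.499 with an estimated correlation). Of 36 Gcn4 target genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone), among the risers ARG4 (log2 1.31) and LYS1 (log2 1.14) (camera adjusted p = 3.20e-10, adjusted p = 0.0655 with an estimated correlation). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 902 genes were higher and 874 lower of 5280. The groups did not overlap for 2213 genes (41.9%), where chance gives 10% for 3 libraries against 3. Genes named here by size of change from a comparison of 2 groups had every library of one group above every library of the other.

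Loss of ELP6 raised GCN4 and many of its targets. ARO5 rose (log2 2.24 ± 0.14, adjusted p = 1.90e-10), and so did GCN4 (log2 2.13 ± 0.05, adjusted p = 5.89e-17) and ATR1 (log2 2.11 ± 0.12, adjusted p = 2.16e-11). PHO5 (log2 -2.89 ± 0.19), TIR1 (log2 -2.49 ± 0.08), FRE4 (log2 -2.23 ± 0.17) and the hexose transporter gene HXT4 (log2 -2.10 ± 0.13) fell. Of 36 Gcn4 target genes, 28 rose and 0 fell (28 and 0 adjusted over the list alone), with a median log2 of 0.61 (camera adjusted p = 3.30e-36, adjusted p = 0.00412 with an estimated correlation), ARG4 (log2 2.00) and HOM3 (log2 0.92) among them. Among 32 proteasome genes, 23 rose and 5 fell, with a median log2 of 0.33 (camera adjusted p = 1.24e-08, adjusted p = 0.0518 with an estimated correlation). Among 137 ribosomal protein genes, 4 rose and 75 fell (4 and 79 adjusted over the list alone), with RPS9A at log2 -0.93 and RPL22B at log2 -0.92 (camera adjusted p = 2.09e-07, adjusted p = 0.58 with an estimated correlation). Of 7 a-cell genes 0 rose and 3 fell in elp6Δ, BAR1 (log2 -0.77), MFA2 (log2 -0.82) and ASG7 (log2 -0.98) (median log2 -0.15, camera adjusted p = 0.0223, adjusted p = 0.441 with an estimated correlation). In ncs2Δ 3 of these 7 rose, MFA1 (log2 0.59), STE2 (log2 0.30) and AGA2 (log2 0.49), and 0 fell (median log2 -0.08, camera adjusted p = 0.571). In elp6Δ 1075 genes were higher and 1114 lower, with no overlap of the groups for 2534 genes (48.0%).

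The changes of ncs2Δ and elp6Δ shared their direction. Over 5277 genes, which are not independent replicates, the fold changes had a Pearson r of 0.772 and a Spearman rho of 0.712, with 611 genes higher in both (n1 × n2 / N gives 184), 597 lower in both (184) and 18 opposite. All comparisons of this kind used the same 3 wild-type libraries, and part of the excess may come from these shared controls, as 3 controls could not be split between the mutants. In 20 simulations without any real change the shared controls alone gave r of 0.521, rho of 0.484 and a covariance of 0.00779, where the real covariance was 0.0937, and 0 shared calls.

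The double deletion ncs2Δ elp6Δ, which carries the MET17 difference described above, had the largest changes. AAD6, an aryl-alcohol dehydrogenase gene whose share of words with other genes was not computed, rose most (log2 4.63 ± 0.27, adjusted p = 1.27e-11). It was followed by HSP12 (log2 4.2 ± 0.16, adjusted p = 2.94e-14) and the sodium pump gene ENA1, for which 90% of its words are shared with its paralogs (log2 3.86 ± 0.22). Next were the mitochondrial aldehyde dehydrogenase gene ALD4 (log2 2.79 ± 0.07), the Hsp70 gene SSA3 (log2 2.76 ± 0.28), the glutathione transferase gene GTT2 (log2 2.67 ± 0.26), NQM1 (log2 2.66 ± 0.16), the aromatic aminotransferase gene ARO9 (log2 2.64 ± 0.07) and ATR1 (log2 2.54 ± 0.11). Phosphate genes led the falls, with SPL2 (log2 -7.11 ± 0.36, adjusted p = 1.42e-12), the high-affinity phosphate transporter gene PHO84 (log2 -6.70 ± 0.37, adjusted p = 4.76e-12), PHO5 (log2 -5.30 ± 0.23) and the polyphosphate synthesis gene VTC3 (log2 -3.61 ± 0.25). PHO84 footprints went from 1429 ± 92.1 to 13.8 ± 1.77 CPM (mean ± standard deviation). The other large falls were in TIR1 (log2 -4.17 ± 0.09), the iron mannoprotein gene FIT1 (log2 -3.09 ± 0.43), the related membrane protein genes MRH1 (log2 -3.04 ± 0.07) and YRO2 (log2 -3.02 ± 0.13), FRE4 (log2 -3.0 ± 0.17) and the mating-type endonuclease gene HO (log2 -2.99 ± 0.06). GCN4 rose (log2 2.32, adjusted p = 2.64e-18).

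In the double deletion 21 of 25 general stress genes rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 of 1.26 (camera adjusted p = 5.01e-16, adjusted p = 0.00102 with an estimated correlation), among them GSY2 (log2 1.57) and TSL1 (log2 1.49). Of 36 Gcn4 targets 26 rose and 5 fell, ARG4 (log2 2.48) and LYS1 (log2 2.04) among the risers (median log2 0.52, camera adjusted p = 3.39e-13, adjusted p = 0.0366 with an estimated correlation). Of 32 proteasome genes 26 rose and 4 fell, with PRE3 at log2 1.17 and RPT3 at log2 1.07 (median log2 0.51, camera adjusted p = 2.90e-11, adjusted p = 0.0366 with an estimated correlation). Of 137 ribosomal protein genes 1 rose and 123 fell (1 and 125 adjusted over the list alone), with RPS9A at log2 -2.04 and RPL22B at log2 -1.83 (median log2 -0.44, camera adjusted p = 4.24e-15, adjusted p = 0.31 with an estimated correlation). The riser was RPS14B, which shares 23.1% of its words. Of 46 ribosome biogenesis genes 6 rose and 31 fell, UTP7 (log2 -0.72) among the latter (camera adjusted p = 0.0128, adjusted p = 0.31 with an estimated correlation). Of 40 respiration genes 28 rose and 0 fell, with COR1 at log2 1.17 and CIT1 at log2 1.15 (camera adjusted p = 1.97e-06, adjusted p = 0.302 with an estimated correlation). Of 16 glycolysis genes 1 rose and 14 fell, PGK1 (log2 -0.92) and HXK2 (log2 -0.88) among them (camera adjusted p = 1.33e-05, adjusted p = 0.31 with an estimated correlation). All 7 a-cell genes were lower, 6 of them over all genes and 7 adjusted over the list alone, with BAR1 at log2 -1.43 (camera adjusted p = 3.30e-04, adjusted p = 0.172 with an estimated correlation). Of the α-cell genes, only STE3 (adjusted p = 0.121) and SAG1 (adjusted p = 0.391) were measured, and neither passed the test.

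Smaller groups moved both ways in the double deletion. Of 24 cytosolic chaperone genes 12 rose and 3 fell, HSP78 (log2 1.47) and HSP82 (log2 0.82) among the risers (camera adjusted p = 0.00659, adjusted p = 0.399 with an estimated correlation). Of 16 endoplasmic reticulum chaperone genes 5 rose, with ERO1 at log2 0.42, and 5 fell, with EUG1 at log2 -0.96 (camera adjusted p = 0.731). Of 19 sulfur and methionine genes 4 rose and 9 fell, MET6 (log2 -1.06) and MET2 (log2 -1.49) among the latter (camera adjusted p = 0.142). MET17 was present in this strain alone, so its part in these changes was not separated from that of the deletions. Of 15 iron genes 2 rose and 7 fell, with ARN2 at log2 -1.54 (camera adjusted p = 0.271). Of 21 genes of the uridine 34 pathway 10 rose, IKI1 (log2 1.05) and TUM1 (log2 0.58) among them, and 3 fell, NCS2 and ELP6 included (camera adjusted p = 0.753). Of 19 ribosome rescue genes 6 rose and 8 fell, with XRN1 at log2 -0.87 (camera adjusted p = 0.731). The fry test asks whether the genes of a set move one way on balance and does not compare them with other genes. By that test the sulfur genes moved down, and those of the uridine 34 pathway did not pass. Of 5280 genes 1595 were higher and 1639 lower, and for 3380 (64.0%) the groups did not overlap. With ncs2Δ the double deletion shared 803 higher genes (n1 × n2 / N gives 272) and 808 lower ones (271), and with elp6Δ 954 (325) and 983 (345), with r of 0.830 and 0.852.

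mRNA fragments of the same strains were compared in the same way. In ncs2Δ the endosomal sorting gene COS12 (log2 2.02 ± 0.37, adjusted p = 0.00503), the phenylpyruvate decarboxylase gene ARO10 (log2 1.57 ± 0.15) and HSP12 (log2 1.54 ± 0.30) rose. PHO5 (log2 -2.45 ± 0.17, adjusted p = 2.03e-06), PHO12, for which 92.2% of its words are shared (log2 -2.22 ± 0.29), TIR1 (log2 -2.21 ± 0.17) and SPL2 (log2 -1.66 ± 0.31) fell. In elp6Δ ARO10 (log2 1.81 ± 0.15), ARO5 (log2 1.70 ± 0.13) and the argininosuccinate lyase gene ARG4 (log2 1.66 ± 0.10) rose. TIR1 (log2 -2.18 ± 0.17), the meiotic telomere gene NDJ1 (log2 -2.03 ± 0.14), PHO12 (log2 -1.95 ± 0.27) and PHO5 (log2 -1.89 ± 0.17) fell. Among 32 proteasome genes 12 rose and 0 fell in each single mutant (18 and 15 risers adjusted over the list alone), with PRE3 at log2 0.55 in ncs2Δ (camera adjusted p = 1.07e-13, adjusted p = 0.0783 with an estimated correlation). Among 137 ribosomal protein genes 0 rose and 17 fell in ncs2Δ (0 and 71 adjusted over the list alone), with RPS9A at log2 -1.04 (camera adjusted p = 3.15e-26, adjusted p = 0.351 with an estimated correlation). Of 36 Gcn4 targets 19 rose and 0 fell in elp6Δ (26 and 1 adjusted over the list alone) and 4 rose and 0 fell in ncs2Δ (5 and 2). In all, 133 genes were higher and 170 lower in ncs2Δ, and 239 higher and 223 lower in elp6Δ, of 5500. The ncs2Δ count of 303 fell to 159 and 161 without wild-type replicates 1 and 2, and to 175 without ncs2Δ replicate 2. The elp6Δ count of 462 fell to 227 and 261 without wild-type replicates 1 and 2, and to 240, 210 and 223 without elp6Δ replicates 1, 2 and 3.

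In mRNA of the double deletion, with its MET17 difference, HSP12 (log2 3.57 ± 0.30, adjusted p = 6.08e-07), COS12 (log2 2.92 ± 0.36) and the cell wall gene HPF1 (log2 2.73 ± 0.20) rose most. ALD4 (log2 2.39 ± 0.14), ARO10 (log2 2.32 ± 0.15), the aspartyl protease gene YPS6 (log2 2.30 ± 0.16), the repressor gene XBP1 (log2 2.17 ± 0.25), ARO9 (log2 2.12 ± 0.15) and the kinase gene KDX1 (log2 1.96 ± 0.10) followed. PHO84 (log2 -6.17 ± 0.43, adjusted p = 1.03e-07), SPL2 (log2 -5.18 ± 0.41), NDJ1 (log2 -3.72 ± 0.16), TIR1 (log2 -3.64 ± 0.19), VTC3 (log2 -3.19 ± 0.29), PHO5 (log2 -2.98 ± 0.18), YRO2 (log2 -2.64 ± 0.13), HO (log2 -2.64 ± 0.09), MRH1 (log2 -2.61 ± 0.11) and the hypoxic eIF5A gene ANB1 (log2 -2.44 ± 0.23) fell most. Of 137 ribosomal protein genes 1 rose and 124 fell (1 and 129 adjusted over the list alone), with a median log2 of -0.56 (camera adjusted p = 3.30e-34, adjusted p = 0.188 with an estimated correlation). Of 25 general stress genes 18 rose and 1 fell, CTT1 (log2 1.21) among the risers and YGP1 (log2 -1.60) the one that fell (camera adjusted p = 3.79e-08, adjusted p = 0.217 with an estimated correlation). In this mRNA comparison 904 genes were higher and 919 lower. Footprint and mRNA changes of the double deletion, which share no library, had r of 0.790, with 683 genes higher in both, 750 lower in both and 34 opposite.

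Translational efficiency, the change of footprints beyond that of mRNA, rose for GCN4 in every mutant, by log2 1.43 ± 0.10 in ncs2Δ (adjusted p = 1.19e-09), 2.12 ± 0.10 in elp6Δ (adjusted p = 1.60e-13) and 2.58 ± 0.10 in ncs2Δ elp6Δ (adjusted p = 1.50e-15). GCN4 mRNA carries short upstream reading frames that govern its translation. The zinc finger gene CMR3 fell in all of them (log2 -1.68 ± 0.28, -1.95 ± 0.28 and -2.68 ± 0.27). In ncs2Δ KDX1 (log2 1.71 ± 0.33), the mating adhesin gene FIG2 (log2 1.39 ± 0.29), the malate synthase gene DAL7 (log2 1.27 ± 0.22) and the citrate synthase gene CIT1 (log2 0.56) also rose. In elp6Δ AAD6 (log2 2.22 ± 0.44), KDX1 (log2 2.03 ± 0.32) and DAL7 (log2 1.29 ± 0.22) rose. The transcription factor genes TOG1 (log2 -1.61 ± 0.37) and MOT3 (log2 -1.01 ± 0.15) and the cortical anchor gene NUM1 (log2 -0.65 ± 0.15) fell. In the double deletion AAD6 (log2 3.23 ± 0.39), YOL029C (log2 3.20 ± 0.88) and SSA3 (log2 2.40 ± 0.34) rose. PHO5 (log2 -2.27 ± 0.38), CSS1 (log2 -2.07 ± 0.58) and MOR1 (log2 -2.01 ± 0.27) fell.

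Among groups, 10 of 36 Gcn4 targets had a higher efficiency in the double deletion and 0 a lower one (14 and 0 adjusted over the list alone), LYS4 (log2 0.76) and ARG4 (log2 0.62) among them (camera adjusted p = 2.38e-04, adjusted p = 0.439 with an estimated correlation). Among 137 ribosomal protein genes 23 were higher, among them RPS17A, which shares 26.3% of its words, and 1 was lower, RPL22B at log2 -0.97 (30 and 1 adjusted over the list alone, camera adjusted p = 1.06e-04, adjusted p = 0.559 with an estimated correlation). Over all 5531 genes 7 were higher and 1 lower in ncs2Δ, 35 and 15 in elp6Δ, and 467 and 205 in the double deletion. The share of higher genes was 87.5%, 70% and 69.5% with TMM scaling and 62.5%, 37.1% and 54.8% with RLE scaling, so the balance of rises and falls depended on the scaling. The ncs2Δ count of 8 went to 5 and 4 without ncs2Δ footprint replicates 1 and 2 and to 14 without mRNA replicate 3 of the wild type or of ncs2Δ. For elp6Δ, 10 of the 12 libraries moved the count of 50, down to 12 without elp6Δ footprint replicate 1 at the lowest and to 29 without replicate 3 at the highest of those 10. For the double deletion the count of 672 fell to 447 without wild-type footprint replicate 2 and to 444 without double-deletion footprint replicate 2.

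**Figure D2:**
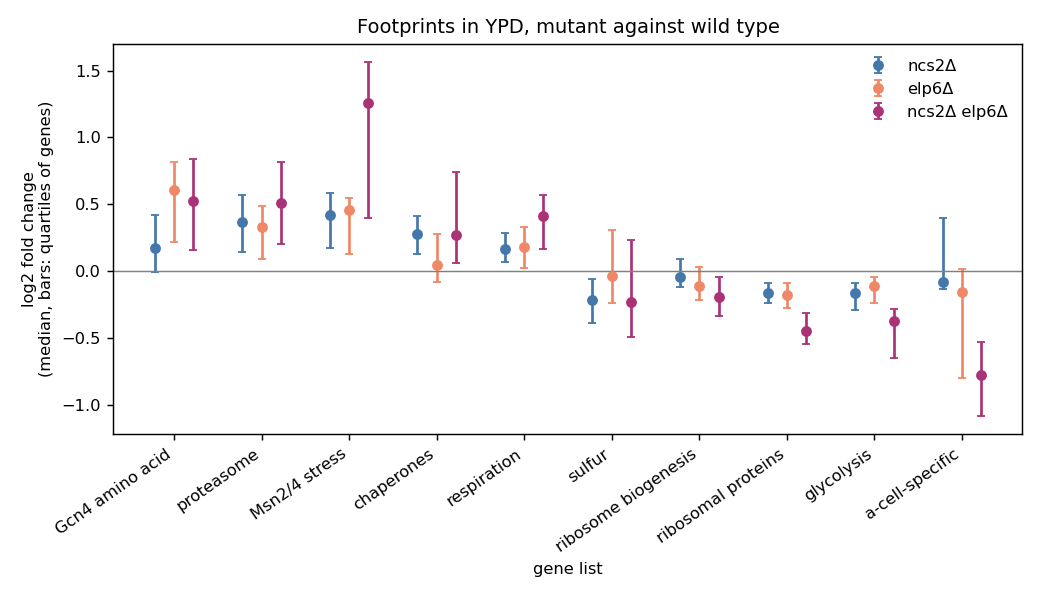
Median (point) and quartiles (bar) of the log2 fold changes of the members of 10 gene groups, footprints of each mutant against the wild type in YPD. The general stress genes had a median of 1.26 in ncs2Δ elp6Δ and 0.42 in ncs2Δ.

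The codons AAA, CAA and GAA are read by the tRNAs that these enzymes modify, and genes rich in them had lower footprints in the mutants. The Spearman correlation of their share with the fold change was -0.0473 in ncs2Δ (adjusted p = 7.87e-04), -0.235 in elp6Δ and -0.150 in ncs2Δ elp6Δ, the last pair with a permutation p of 1.00e-05, the smallest that the permutations can give. For mRNA the values were -0.0352, -0.213 and -0.103, and for translational efficiency -0.0396, -0.0822 and -0.0854. Genes are not independent replicates, and the adjustment covered 12 comparisons. For ncs2Δ without cycloheximide the correlation was -0.170, more negative than with the drug. With an empty plasmid in selective medium it was -0.148 for ncs2Δ and 0.0450 for elp6Δ (adjusted p = 0.00136), so the sign for elp6Δ was the opposite of that in YPD. Of the 529 genes in the top 10% by this codon share, 25 rose and 245 fell in elp6Δ footprints (camera adjusted p = 7.65e-11, adjusted p = 0.332 with an estimated correlation). In ncs2Δ 60 rose and 121 fell (median log2 -0.03, camera adjusted p = 0.0355, adjusted p = 0.784 with an estimated correlation). In the double deletion 76 rose and 247 fell (camera adjusted p = 4.27e-04, adjusted p = 0.714 with an estimated correlation). In elp6Δ with the empty plasmid 108 rose and 61 fell (camera adjusted p = 0.292). With each codon taken alone, the correlation of GAA with the efficiency was positive in ncs2Δ (0.0473, adjusted p = 5.47e-04) and did not pass in elp6Δ (0.0110, adjusted p = 0.453) or the double deletion (0.00229, adjusted p = 0.867). That of AAA with ncs2Δ mRNA was positive (0.0632, adjusted p = 1.33e-05).

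Without cycloheximide in the culture or the lysis buffer the ncs2Δ profile kept its main genes. HSP12 (log2 2.07 ± 0.24, adjusted p = 3.03e-06), FIG2 (log2 2.01 ± 0.20), SER3 (log2 1.66 ± 0.12) and ALD4 (log2 1.59 ± 0.10) rose. PHO5 (log2 -3.31 ± 0.23, adjusted p = 5.50e-09), TIR1 (log2 -2.08 ± 0.10), FRE4 (log2 -2.02 ± 0.15) and YNL040W, which encodes a protein similar to alanyl-tRNA synthetases (log2 -1.77 ± 0.10), fell. Of 32 proteasome genes 22 rose and 2 fell, with RPN2 at log2 0.66 and RPT3 at log2 0.65 (camera adjusted p = 3.44e-12, adjusted p = 0.0272 with an estimated correlation). Of 137 ribosomal protein genes 1 rose and 66 fell (1 and 79 adjusted over the list alone), with RPS9A at log2 -1.38 (camera adjusted p = 5.26e-10, adjusted p = 0.446 with an estimated correlation). In all 846 genes were higher and 840 lower. These libraries are not shared with those made with the drug, and the fold changes of the pair of experiments had r of 0.826 and rho of 0.790 over 5250 genes, with 626 higher in both (144 from n1 × n2 / N), 607 lower in both (139) and 1 opposite. The interaction of drug and strain had 0 genes in edgeR's test and 0 in DESeq2, with 194 genes of 5262 at unadjusted p < 0.05.

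In the wild type itself, leaving out cycloheximide raised glycolysis and ribosomal protein footprints. EFT1, which encodes elongation factor 2 and shares 95.5% of its words with its paralog (log2 0.78 ± 0.08, adjusted p = 1.60e-05), rose with RPL35A (log2 0.79 ± 0.13), RPL35B (log2 0.79 ± 0.20), which share 86.0%, and RPL41A, which shares 82.4% (log2 0.86 ± 0.22). YDR034C-A (log2 -1.11 ± 0.21), MIN9 (log2 -0.79 ± 0.15), the iron-sulfur regulator gene BOL2 (log2 -0.75 ± 0.08) and CNL1 (log2 -0.71 ± 0.14) fell. Of 16 glycolysis genes 12 rose and 0 fell (16 and 0 adjusted over the list alone), ADH1 (log2 0.46) and PGI1 (log2 0.37) among them (camera adjusted p = 6.11e-16, adjusted p = 0.22 with an estimated correlation). Among 137 ribosomal protein genes 47 rose and 1 fell (62 and 2 adjusted over the list alone), with RPS21B at log2 0.52 (camera adjusted p = 1.43e-20, adjusted p = 0.393 with an estimated correlation). The count of 427 genes (279 higher, 148 lower) fell to 163 without YPD replicate 2 and to 216 without replicate 3 of the libraries made without the drug.

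Diamide, which oxidises thiols, changed most of the footprint profile of the wild type within 30 min. FAT3, a fatty acid uptake gene, rose most (log2 8.46 ± 0.17, adjusted p = 5.56e-20), followed by HSP12 (log2 8.23 ± 0.18), AAD6 (log2 8.14 ± 0.14), the NADPH oxidoreductase gene OYE3 (log2 8.11 ± 0.14) and the glycerol dehydrogenase gene GCY1 (log2 7.86 ± 0.16). PHM7 (log2 7.82 ± 0.19), the reticulon gene RTN2 (log2 7.62 ± 0.17), ATO2 (log2 7.38 ± 0.26), the stress gene DDR2 (log2 7.03 ± 0.17) and the phosphatase regulator gene GAC1 (log2 7.02 ± 0.17) came next. The ribosome assembly genes SYO1 (log2 -7.55 ± 0.21, adjusted p = 6.82e-18), DHR2 (log2 -7.49 ± 0.24), NSR1 (log2 -7.34 ± 0.11) and LTV1 (log2 -7.08 ± 0.16) fell most. The next were the adenine deaminase gene AAH1 (log2 -6.99 ± 0.15), the repressor gene TOD6 (log2 -6.02 ± 0.17), FAF1 (log2 -6.01 ± 0.17), ENP2 (log2 -5.88 ± 0.16), HCA4 (log2 -5.84 ± 0.10) and the iron transporter gene FET4 (log2 -5.68 ± 0.19). All 22 measured oxidative stress genes of the Yap1 factor rose (median log2 1.89, camera adjusted p = 6.91e-14, adjusted p = 0.0272 with an estimated correlation), among them the peroxiredoxin gene TSA2 (log2 5.57). All 25 general stress genes rose (median log2 4.64, camera adjusted p = 9.57e-40, adjusted p = 0.0165 with an estimated correlation), with PGM2 at log2 6.91. All 32 proteasome genes rose (median log2 1.03, camera adjusted p = 1.57e-08, adjusted p = 0.0272 with an estimated correlation). Of 24 cytosolic chaperone genes 23 rose, with SSA4 at log2 6.17 (camera adjusted p = 4.22e-11, adjusted p = 0.0852 with an estimated correlation). All 46 ribosome biogenesis genes fell (median log2 -3.61, camera adjusted p = 5.95e-55, adjusted p = 0.0165 with an estimated correlation). Among 137 ribosomal protein genes 136 fell (median log2 -1.69, camera adjusted p = 1.68e-28, adjusted p = 0.121 with an estimated correlation). Of 20 sulfur and methionine genes 16 rose, MET3 (log2 4.22) among them, and 4 fell. In total 2151 genes were higher and 2206 lower of 5375.

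In ncs2Δ diamide moved 2230 genes up and 2251 down, and the changes followed those of the wild type (r of 0.978, 9 genes opposite). FAT3 (log2 9.73 ± 0.17), PHM7 (log2 9.11 ± 0.18), ALD3, an aldehyde dehydrogenase gene that shares 51.7% of its words (log2 8.87 ± 0.21), and FMP45 (log2 8.85 ± 0.16) rose most. DHR2 (log2 -8.17 ± 0.22), NSR1 (log2 -8.06 ± 0.11), SYO1 (log2 -7.49 ± 0.18) and AAH1 (log2 -7.34 ± 0.15) fell most. The interaction of diamide and strain was positive for the membrane gene FMP45 (log2 1.87 ± 0.48, adjusted p = 0.0148), the cell wall gene YGP1 (log2 1.77 ± 0.25, adjusted p = 1.07e-04), HBT1 (log2 1.52 ± 0.34) and the chaperone gene SSE2 (log2 1.39 ± 0.09, adjusted p = 1.88e-08). It was negative for AAD6 (log2 -2.27 ± 0.29, adjusted p = 4.38e-05), PHO84 (log2 -1.53 ± 0.36), the ribosome assembly gene BFR2 (log2 -1.41 ± 0.27) and ATR1 (log2 -1.36 ± 0.12). The proteasome genes rose less in ncs2Δ (median log2 0.63), with a negative interaction for 26 of 32 and a positive one for 0 (31 and 0 adjusted over the list alone), PUP3 (log2 -0.59) and PRE3 (log2 -0.58) among them (camera adjusted p = 2.48e-20, adjusted p = 0.00277 with an estimated correlation). The median level of the proteasome genes was 483 CPM in ncs2Δ and 500 in the wild type under diamide, and 283 and 219 in YPD. Their levels thus differed mainly before the drug. The ribosome biogenesis genes fell further, with a negative interaction for 33 of 46 and a positive one for 1 (38 and 1 adjusted over the list alone), NOG1 (log2 -1.34) and ERB1 (log2 -0.88) among the former (camera adjusted p = 6.75e-21, adjusted p = 0.0219 with an estimated correlation). The interaction was positive for 177 genes and negative for 467.

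mRNA under diamide also showed rises of stress genes and falls of ribosome genes. HSP12 (log2 8.08 ± 0.28, adjusted p = 2.04e-14), OYE3 (log2 7.30 ± 0.18), the thiolase gene POT1 (log2 7.17 ± 0.26) and DDR2 (log2 6.79 ± 0.17) rose most. The helicase gene DBP2 (log2 -6.75 ± 0.14, adjusted p = 2.38e-16), AAH1 (log2 -6.74 ± 0.17), SYO1 (log2 -6.29 ± 0.20) and NSR1 (log2 -6.15 ± 0.18) fell most, among 2017 higher and 2014 lower genes of 5541. All 25 general stress genes rose (median log2 3.47, camera adjusted p = 2.40e-31, adjusted p = 0.0149 with an estimated correlation). All 46 ribosome biogenesis genes fell (median log2 -3.28, camera adjusted p = 1.00e-44, adjusted p = 0.00353 with an estimated correlation). Among 137 ribosomal protein genes 0 rose and 136 fell (median log2 -2.05, camera adjusted p = 1.97e-43, adjusted p = 0.0592 with an estimated correlation). Of 20 sulfur and methionine genes 14 rose and 3 fell in this mRNA, with a median log2 of 0.66 against 1.67 in footprints (camera adjusted p = 0.0328, adjusted p = 0.324 with an estimated correlation). Footprint and mRNA changes had r of 0.947, with 15 genes opposite. The interaction with ncs2Δ in mRNA was positive for 60 genes, led by the transketolase gene TKL2 (log2 3.03 ± 0.50, adjusted p = 0.00241), ALD3 (log2 2.80 ± 0.27), YGP1 (log2 1.94 ± 0.17) and GND2 (log2 1.82 ± 0.27). It was negative for 126, led by INA1 (log2 -1.52 ± 0.18, adjusted p = 1.22e-04), PEX21 (log2 -1.30 ± 0.23), ACM1 (log2 -1.26 ± 0.27) and HO (log2 -1.25 ± 0.14). The general stress genes had a positive interaction for 7 of 25 and a negative one for 0 (13 and 0 adjusted over the list alone, camera adjusted p = 1.35e-20, adjusted p = 0.0389 with an estimated correlation). Among the proteasome genes 0 had an interaction in either direction (camera adjusted p = 5.33e-06, adjusted p = 0.155 with an estimated correlation). The count of 186 fell to 100 and 108 without wild-type YPD replicates 1 and 2, to 118 without wild-type diamide replicate 1, to 117 without ncs2Δ YPD replicate 2 and to 98 without ncs2Δ diamide replicate 2.

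Efficiency under diamide in the wild type rose most for AAD4, which shares 29.1% of its words (log2 6.02 ± 1.04), the catalase gene CTA1 (log2 4.6 ± 0.52), SSA3 (log2 4.55 ± 0.24, adjusted p = 9.85e-11) and FAT3 (log2 4.49 ± 0.24). It fell most for the alcohol acetyltransferase gene ATF1 (log2 -4.91 ± 0.22, adjusted p = 5.55e-12), the zinc transporter gene ZRT1 (log2 -2.72 ± 0.34) and the ribosome assembly genes RIO1 (log2 -2.66 ± 0.18) and ESF1 (log2 -2.35 ± 0.18). Of 20 sulfur and methionine genes 16 were higher and 0 lower, MET3 (log2 2.48) and MET5 (log2 1.67) among them (median log2 0.74, camera adjusted p = 1.03e-13, adjusted p = 0.0192 with an estimated correlation). Of 25 general stress genes 20 were higher and 0 lower, RTN2 (log2 4.36) among them (median log2 0.76, camera adjusted p = 1.13e-23, adjusted p = 0.0192 with an estimated correlation). Over all 5520 genes 759 were higher and 163 lower. The share of higher genes was 82.3% with TMM and 58.8% with RLE scaling, which shifted the median of all genes by -0.133.

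Rapamycin, which inhibits the TORC1 kinase, raised nitrogen genes in the wild type. The allantoate permease gene DAL5 (log2 8.45 ± 0.41, adjusted p = 6.71e-13), the ammonium permease gene MEP2 (log2 7.97 ± 0.24), the general amino acid permease gene GAP1 (log2 7.11 ± 0.16, adjusted p = 1.55e-17) and the proline permease gene PUT4 (log2 7.05 ± 0.39) rose most. The urea transporter gene DUR3 (log2 6.70 ± 0.23), the oligopeptide transporter gene OPT2 (log2 6.66 ± 0.30), DAL7 (log2 5.96 ± 0.31), the urea amidolyase gene DUR12 (log2 5.36 ± 0.18) and DAL3 (log2 4.81 ± 0.30) followed. DAL80, which encodes a repressor of these genes, had 31.6 ± 9.59 CPM under rapamycin and 0.0822 ± 0.0803 in YPD. GFD2 (log2 -4.75 ± 0.24, adjusted p = 1.01e-12), TOD6 (log2 -4.30 ± 0.15) and the deubiquitination inhibitor gene RFU1 (log2 -4.08 ± 0.25) fell most. The ribosome assembly genes DHR2 (log2 -3.98 ± 0.20), NOG2 (log2 -3.93 ± 0.17), NSR1 (log2 -3.74 ± 0.18), RCL1 (log2 -3.53 ± 0.14) and SYO1 (log2 -3.46 ± 0.15), UPA1 (log2 -3.88 ± 0.17) and ATC1 (log2 -3.70 ± 0.19) followed. All 20 genes under nitrogen catabolite repression rose (median log2 3.66, camera adjusted p = 2.15e-25, adjusted p = 0.033 with an estimated correlation), as did all 7 retrograde genes, with CIT2 at log2 2.85 (camera adjusted p = 3.60e-17, adjusted p = 0.00505 with an estimated correlation). All 46 ribosome biogenesis genes fell (median log2 -2.36, camera adjusted p = 2.55e-40, adjusted p = 0.0581 with an estimated correlation). Of 137 ribosomal protein genes 132 fell and 1 rose (median log2 -0.82, camera adjusted p = 3.42e-19, adjusted p = 0.242 with an estimated correlation), RPL33B (log2 -1.17) among them. In all 1929 genes were higher and 1800 lower of 5339.

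Both mutants responded to rapamycin, and some groups moved less. In ncs2Δ PUT4 (log2 7.49 ± 0.37), MEP2 (log2 7.44 ± 0.24) and GAP1 (log2 6.53 ± 0.16) rose, and DAL5 went from 0.0564 to 47.4 CPM. GFD2 (log2 -4.25 ± 0.19), TOD6 (log2 -3.86 ± 0.15), DHR2 (log2 -3.31 ± 0.18) and RFU1 (log2 -3.18 ± 0.22) fell, with 1759 genes higher and 1707 lower. In elp6Δ PUT4 (log2 8.62 ± 0.36) and MEP2 (log2 7.37 ± 0.23) rose, and DAL5 went from 0.223 to 106 and DAL80 from 0.0432 to 35.8 CPM. GFD2 (log2 -4.44 ± 0.20), TOD6 (log2 -4.06 ± 0.15), RFU1 (log2 -3.65 ± 0.24) and NOG2 (log2 -3.13 ± 0.15) fell, with 1718 higher and 1782 lower. The median change of the ribosomal protein genes was -0.48 in ncs2Δ and -0.58 in elp6Δ, against -0.82 in the wild type. Their interaction was positive for 19 of 137 in ncs2Δ and negative for 0 (118 and 0 adjusted over the list alone, camera adjusted p = 9.73e-41, adjusted p = 0.172 with an estimated correlation), RPP0 (log2 0.39) and RPS27A (log2 0.54) among them. In elp6Δ it was positive for 20 and negative for 0 (58 and 0 adjusted over the list alone, camera adjusted p = 1.74e-18, adjusted p = 0.495 with an estimated correlation), RPP2B (log2 0.64) among them. Retrograde genes rose less, with a negative interaction for 5 of 7 in ncs2Δ, ACO1 (log2 -0.61) among them (camera adjusted p = 1.77e-12, adjusted p = 0.00873 with an estimated correlation), and for 4 of 7 in elp6Δ (camera adjusted p = 5.37e-08, adjusted p = 0.0444 with an estimated correlation). Their median level in YPD was 265 CPM in ncs2Δ, 306 in elp6Δ and 207 in the wild type. Under rapamycin it was 909, 955 and 1020 CPM, so part of the difference lay at the start.

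**Figure D3:**
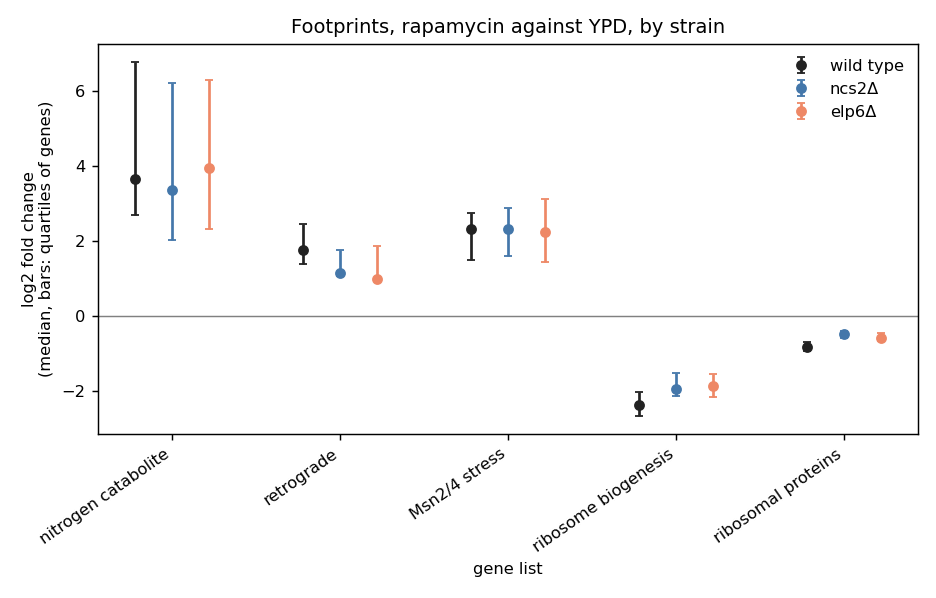
Median (point) and quartiles (bar) of the log2 fold changes of the members of 5 gene groups, footprints under rapamycin against YPD in the wild type, ncs2Δ and elp6Δ. The ribosomal protein median was -0.82 in the wild type and -0.48 in ncs2Δ.

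Single genes with a positive interaction of rapamycin and ncs2Δ were UPA1 (log2 1.30 ± 0.25, adjusted p = 0.00907), the ribosomal RNA methyltransferase gene BMT2 (log2 1.09 ± 0.25), the ribosome assembly gene NOC4 (log2 1.08 ± 0.17) and the uracil permease gene FUR4 (log2 1.01 ± 0.23). ARO10 (log2 -1.0 ± 0.14, adjusted p = 7.65e-04), DUR12 (log2 -0.84 ± 0.22), the pyruvate carboxylase gene PYC1 (log2 -0.80 ± 0.15) and the polyubiquitin gene UBI4 (log2 -0.77 ± 0.14) had a negative one. With elp6Δ the positive ones were FAF1 (log2 1.30 ± 0.20, adjusted p = 0.00104), UPA1 (log2 1.17 ± 0.25), SRP40 (log2 1.17 ± 0.19) and the RNA surveillance gene AIR1 (log2 1.09 ± 0.19). The negative ones were ARO10 (log2 -1.10 ± 0.14, adjusted p = 3.68e-04), ARO9 (log2 -0.93 ± 0.12), PDH1 (log2 -0.84 ± 0.16) and PYC1 (log2 -0.83 ± 0.15). The ncs2Δ interaction held 116 positive and 32 negative genes, and the elp6Δ one 209 and 100. These counts depended on single libraries. Leaving out 11 of 12 libraries in turn moved the 148 of ncs2Δ to between 25 (without ncs2Δ rapamycin replicate 2) and 428 (without ncs2Δ rapamycin replicate 1), and 10 of 12 moved the 309 of elp6Δ to between 56 (without wild-type rapamycin replicate 1) and 591 (without wild-type YPD replicate 3).

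In mRNA under rapamycin DAL80 (log2 6.93 ± 0.38, adjusted p = 7.58e-09), GAP1 (log2 6.74 ± 0.18), MEP2 (log2 6.52 ± 0.23) and PUT4 (log2 5.46 ± 0.21) rose. The ribosome assembly genes NOP14 (log2 -4.56 ± 0.27, adjusted p = 1.48e-08), MRD1 (log2 -4.48 ± 0.23), NSR1 (log2 -4.41 ± 0.20) and DBP3 (log2 -4.36 ± 0.24) fell, among 1562 higher and 1552 lower genes of 5491. The interaction with ncs2Δ had 0 genes in edgeR's test, with 193 at unadjusted p < 0.05, and 8 in DESeq2. It was also 8 in edgeR's test without wild-type rapamycin replicate 3, which stood apart from the other replicates. Efficiency under rapamycin rose for DAL5 (log2 5.52 ± 0.51, adjusted p = 1.96e-04), DAL7 (log2 3.51 ± 0.34), the glutathione transferase gene GTO1 (log2 2.90 ± 0.49) and AMD2 (log2 2.85 ± 0.34). It fell for the ferric reductase gene FRE3 (log2 -1.87 ± 0.43, adjusted p = 0.0332), NAF1 (log2 -1.25 ± 0.22), NCS6, which encodes the partner of Ncs2 (log2 -1.19 ± 0.21, adjusted p = 0.0104), and CPS1 (log2 -1.17 ± 0.22). Of 46 ribosome biogenesis genes 14 were higher and 0 lower (33 and 1 adjusted over the list alone), RRP5 (log2 2.31) and UTP20 (log2 1.51) among them (camera adjusted p = 1.65e-15, adjusted p = 0.289 with an estimated correlation). Of 5477 genes 201 were higher and 18 lower, and this balance was not stable. It turned to 129 higher and 259 lower without wild-type rapamycin mRNA replicate 1 and to 376 higher and 728 lower without replicate 2, and DESeq2 gave 284 higher and 214 lower. The share of higher genes was 91.8% with TMM and 78.9% with RLE scaling, which shifted the median of all genes by -0.113. Each of the 12 libraries moved the count of 219 when left out, to between 44 (without wild-type YPD mRNA replicate 2) and 1104 (without wild-type rapamycin mRNA replicate 2).

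In selective medium with an empty plasmid, iron genes rose in ncs2Δ. The mannoprotein genes FIT3 (log2 3.77 ± 0.27, adjusted p = 1.69e-08) and FIT2 (log2 2.99 ± 0.19) rose, with TKL2 (log2 3.38 ± 0.35) and ALD3 (log2 3.01 ± 0.29). PHO84 (log2 -3.15 ± 0.52), ATF1 (log2 -1.48 ± 0.21), YNL040W (log2 -1.27 ± 0.13) and ATF2 (log2 -1.26 ± 0.16) fell. Of 15 iron genes 14 rose and 0 fell (median log2 1.37, camera adjusted p = 1.76e-21, adjusted p = 0.0316 with an estimated correlation). Of 25 general stress genes 24 rose and 0 fell (median log2 1.17, camera adjusted p = 1.33e-20, adjusted p = 0.159 with an estimated correlation). Among 32 proteasome genes 23 rose and 2 fell (camera adjusted p = 1.71e-13, adjusted p = 0.00475 with an estimated correlation). In all 844 genes were higher and 735 lower of 5286. Against ncs2Δ in YPD, with no shared library, r was 0.619.

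In elp6Δ with the empty plasmid, general stress genes rose and a-cell genes fell. Of 25 general stress genes 19 rose and 1 fell (median log2 0.73, camera adjusted p = 3.19e-07, adjusted p = 0.44 with an estimated correlation). NQM1 (log2 2.99 ± 0.27, adjusted p = 1.62e-07), the hexose transporter gene HXT5 (log2 2.59 ± 0.36), GRE1 (log2 2.37 ± 0.36), MNC1 (log2 2.32 ± 0.29), ALD3 (log2 2.22 ± 0.31), PHM7 (log2 2.00 ± 0.32), the alcohol dehydrogenase gene ADH2 (log2 1.85 ± 0.18), HSP12 (log2 1.76 ± 0.18), ARO10 (log2 1.69 ± 0.09) and FIT3 (log2 1.69 ± 0.29) rose. The a-agglutinin genes AGA1 (log2 -2.53 ± 0.12, adjusted p = 4.76e-11) and AGA2 (log2 -1.35 ± 0.11), FIG2 (log2 -1.88 ± 0.19), AFB1, which encodes the a-pheromone blocker (log2 -1.56 ± 0.19), PHO84 (log2 -2.10 ± 0.46), YDR034C-A (log2 -1.95 ± 0.22), YRO2 (log2 -1.47 ± 0.12), ATF2 (log2 -1.42 ± 0.16), SRD1 (log2 -1.40 ± 0.17) and YGP1 (log2 -1.30 ± 0.13) fell. All 7 a-cell genes fell (median log2 -0.72, camera adjusted p = 4.09e-11, adjusted p = 0.00226 with an estimated correlation), BAR1 (log2 -1.05) among them. The 2 measured α-cell genes, too few for a list test, had a median log2 of -1.19 at low levels (median 4.32 against 5.61 CPM). A fall limited to a-cell genes was thus not shown. Of 32 proteasome genes 23 rose and 2 fell (camera adjusted p = 6.87e-15, adjusted p = 0.00226 with an estimated correlation). Of 15 iron genes 1 rose and 3 fell (camera adjusted p = 0.489). In all 1007 genes were higher and 973 lower, and against elp6Δ in YPD r was 0.478, with 113 genes opposite.

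A plasmid named tEKQ in the labels, a name that points to tRNAs for glutamate, lysine and glutamine (E, K and Q), was compared with the empty plasmid. In ncs2Δ it raised ZRT1 (log2 3.18 ± 0.79, adjusted p = 0.023), its zinc-responsive activator gene ZAP1 (log2 1.18 ± 0.31), the ferric reductase gene FRE1 (log2 1.02 ± 0.22) and HBN1 (log2 1.00 ± 0.16). It lowered TKL2 (log2 -1.40 ± 0.29), FMP16 (log2 -1.33 ± 0.34), ALD3 (log2 -1.13 ± 0.24) and HSP12 (log2 -1.02 ± 0.17, adjusted p = 0.00223). Among 32 proteasome genes 14 fell and 1 rose (18 and 2 adjusted over the list alone), with RPT3 at log2 -0.40 (camera adjusted p = 6.82e-11, adjusted p = 0.0178 with an estimated correlation). In elp6Δ it raised PHO84 (log2 2.39 ± 0.45, adjusted p = 0.00829), the inositol synthesis gene INO1 (log2 1.67 ± 0.27), YGP1 (log2 1.08 ± 0.12) and YRO2 (log2 1.01 ± 0.12). It lowered FIT3 (log2 -1.08 ± 0.27), FIT2 (log2 -0.75 ± 0.19), ARO9 (log2 -0.68 ± 0.08) and EEB1 (log2 -0.66 ± 0.17). Of 20 sulfur and methionine genes 8 rose and 0 fell there (13 and 0 adjusted over the list alone), MET3 (log2 0.85) among them (camera adjusted p = 1.40e-13, adjusted p = 0.0365 with an estimated correlation). The counts were 140 higher and 174 lower in ncs2Δ, and 60 and 42 in elp6Δ. The 314 of ncs2Δ fell to 203 and 139 without replicates 2 and 3 of the empty plasmid, and to 141 and 126 without replicates 2 and 3 of tEKQ. The 102 of elp6Δ went to 31 and 30 without replicates 2 and 3 of the empty plasmid, and to 39, 65 and 201 without replicates 1, 2 and 3 of tEKQ.

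Against the wild type with the empty plasmid, ncs2Δ with tEKQ had 212 higher and 95 lower genes, and elp6Δ with tEKQ 778 and 724. These groups differ in both strain and plasmid, and the wild type with tEKQ was not analysed here. A return of a mutant towards the wild type was thus not separated from an effect of tEKQ in any strain. In ncs2Δ FIT3 (log2 4.43 ± 0.27, adjusted p = 2.15e-09), the siderophore transporter gene ARN2 (log2 3.66 ± 0.23), FIT2 (log2 3.44 ± 0.19) and ALD3 (log2 1.88 ± 0.32) stayed higher. PHO84 (log2 -1.54 ± 0.44), CMS1 (log2 -0.81 ± 0.13), SRO77 (log2 -0.81 ± 0.12) and EFM3 (log2 -0.79 ± 0.20) stayed lower. All 15 iron genes were higher (median log2 1.8, camera adjusted p = 2.83e-93, adjusted p = 2.84e-04 with an estimated correlation). In elp6Δ HXT5 (log2 3.11 ± 0.34), GRE1 (log2 3.06 ± 0.32), NQM1 (log2 2.88 ± 0.26) and the zinc-regulated gene ZPS1 (log2 4.66 ± 1.21, adjusted p = 0.00777), which varied between libraries (133 ± 208 CPM), were higher. AGA1 (log2 -2.23 ± 0.11), FIG2 (log2 -2.20 ± 0.18), YDR034C-A (log2 -1.53 ± 0.20) and AGA2 (log2 -1.33 ± 0.10) were lower. All 7 a-cell genes were lower (camera adjusted p = 2.26e-16, adjusted p = 4.33e-04 with an estimated correlation). The count of 307 in ncs2Δ fell to 141 and 128 without wild-type replicates 1 and 2, and to 159 and 136 without tEKQ replicates 1 and 3.

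Footprints of tut-1 nematodes of the fourth larval stage were richer in yolk, eggshell and sperm genes than those of N2, with 2 libraries against 2. Shared words were not computed for nematode genes, so the counts of single members of gene families are uncertain. Yolk and eggshell genes mark the adult stage. The yolk protein genes vit-2 (5909 ± 4899 against 21 ± 15.8 CPM) and vit-5 (1172 ± 1163 against 0.928 ± 1.31), the eggshell genes perm-4 (1062 ± 14.2 against 15 ± 9.72) and perm-2 (655 against 8.70), the yolk receptor gene rme-2 (68.6 against 1.70) and the sperm gene msp-78 (127 against 1.43) were higher. Genes without any N2 read were Y62H9A.4 (142 CPM in tut-1), W02D9.7 (71.0 ± 3.02), the uterine lumen gene ule-1 (69.4 ± 28.4), ZK813.2 (48.9 ± 11.5), K07A1.6 (35.4 ± 9.62) and the transthyretin-related gene ttr-42 (21.2 ± 10.1), where 3 reads would have been 0.233 and 1.83 CPM in the N2 libraries. Y37D8A.19 rose (log2 10.63 ± 0.53, adjusted p = 4.12e-05), and Y62H9A.3 (117), F55B11.3 (107) and C10G8.4 (102 CPM) were at 0.0387 in N2. The cuticle collagen genes col-41 (log2 -5.52 ± 0.54, adjusted p = 7.59e-04), col-54 (log2 -4.36 ± 0.45) and col-90 (log2 -3.81 ± 0.42), the cuticle shape genes dpy-1 (log2 -4.28 ± 0.36) and dpy-6 (log2 -2.69 ± 0.25), the acyltransferase gene oac-29 (log2 -4.81 ± 0.74), R10E4.1 (log2 -4.09 ± 0.48), the carbonic anhydrase gene bca-1 (log2 -4.01 ± 0.32), T19C3.3 (log2 -3.16 ± 0.46) and F19H8.2 (log2 -2.77 ± 0.34) fell.

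All 22 major sperm protein genes rose in tut-1 footprints (median log2 4.39, and 4.34 with the 1 member without N2 reads at its bound, camera adjusted p = 1.31e-33, adjusted p = 0.145 with an estimated correlation). All 6 yolk genes (median log2 7.87, camera adjusted p = 3.97e-08, adjusted p = 0.434 with an estimated correlation) and all 9 oocyte and eggshell genes (median log2 5.94, camera adjusted p = 7.14e-07, adjusted p = 0.434 with an estimated correlation) rose. Of 111 collagen genes 34 rose, col-19 (1180 against 3.72 CPM) and col-81 (1771 against 4.57) among them, and 12 fell (39 and 14 adjusted over the list alone, camera adjusted p = 5.23e-05, adjusted p = 0.32 with an estimated correlation). Of 84 lysozyme and lectin genes 24 rose, clec-41 (log2 2.25) among them, and 3 fell (30 and 4 adjusted over the list alone, camera adjusted p = 7.02e-04, adjusted p = 0.607 with an estimated correlation). Of 13 cytosolic heat shock genes 2 rose, sip-1 (log2 2.84) and hsp-43 (log2 1.70), and 0 fell (camera adjusted p = 0.571). Of 73 ribosomal protein genes 1 rose, rpl-42 (log2 3.91). Of 7 organelle chaperone genes, 12 oxidative detoxification genes and 6 genes of the uridine 34 pathway 0 passed the test, in a comparison that found 0 of 50 simulated changes of 2-fold. This holds for tut-1 itself (log2 -0.83, adjusted p = 0.115), which had 17.1 and 17.2 CPM in the mutant and 35.5 and 28.1 in N2. In all 1448 genes were higher and 234 lower of 12444, and the count of 1682 fell to 511 without tut-1 replicate 1, the deeper library of its pair.

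**Figure D4:**
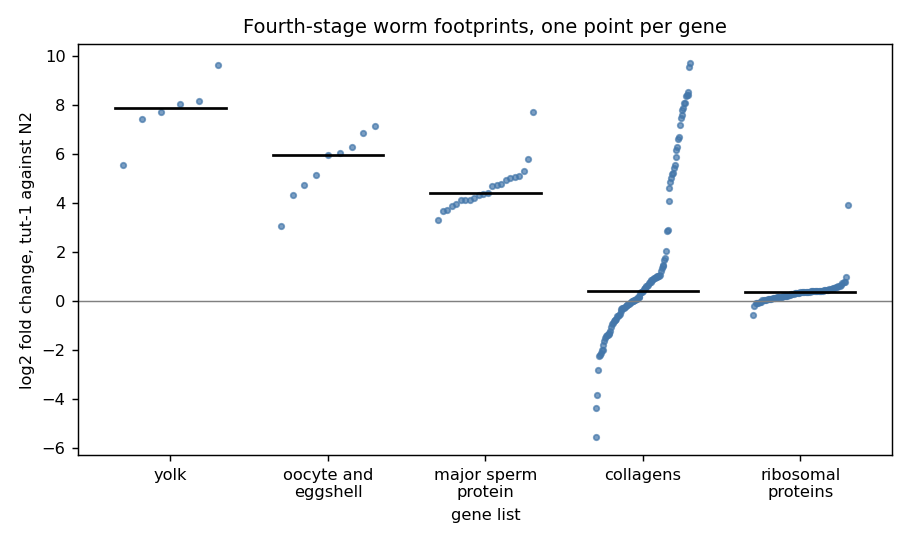
Log2 fold changes of tut-1 against N2 footprints, one point per gene and a line at the median, for yolk, oocyte and eggshell, major sperm protein, collagen and ribosomal protein genes. The yolk median was 7.87 and the ribosomal protein median 0.36.

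In mRNA of adult tut-1 elpc-1 nematodes sperm genes were higher than in N2. The 2 N2 libraries differed more from each other (r of 0.971) than the 2 mutant libraries did (0.993). F40D4.13 (log2 6.06 ± 0.44, adjusted p = 5.17e-05), the palmitoyltransferase gene dhhc-13 (log2 4.92 ± 0.49), the sperm membrane fusion gene fer-1 (log2 4.92 ± 0.47), B0393.4 (log2 4.90 ± 0.43), the glutathione transferase gene gst-24 (log2 4.88 ± 0.45), spc-2 (log2 4.88 ± 0.51), the Argonaute gene wago-10 (log2 4.77 ± 0.40) and ZK1010.5 (log2 4.76 ± 0.43) rose. ZK228.3 (38.7 against 0.0115 CPM) and ZK228.4 (52.7 against 0.0364) were nearly absent from N2. The lectin gene clec-266 (log2 -3.89 ± 0.45, adjusted p = 1.09e-04), the caveolin gene cav-1 (log2 -3.06 ± 0.39), the mitochondrial gene ND6 (log2 -2.99 ± 0.53), T09B9.1 (log2 -2.77 ± 0.44), Y45F10C.4 (log2 -2.76 ± 0.41), C09B8.4 (log2 -2.57 ± 0.42), T09A5.15 (log2 -2.35 ± 0.45), dod-3 (log2 -2.31 ± 0.38), F08B6.1 (log2 -2.28 ± 0.46) and C17E4.2 (log2 -2.28 ± 0.41) fell. tut-1 itself fell (log2 -1.87, adjusted p = 0.00239). elpc-1, the other mutated gene, did not pass, with 85.2 and 91.0 CPM in the mutant and 73.3 and 134 in N2 (adjusted p = 0.681). Of 27 major sperm protein genes 26 rose and 0 fell (27 and 0 adjusted over the list alone, median log2 2.87, camera adjusted p = 1.19e-16, adjusted p = 0.958 with an estimated correlation). Of 6 yolk genes (median log2 0.62) and 10 oocyte and eggshell genes (median log2 -0.58) 0 passed the test (camera adjusted p = 0.477 and 0.286). In simulated data only 2 of 50 changes of 2-fold were found in this comparison, so a change of these genes was not excluded. In all 2071 genes were higher and 1051 lower of 15278. The count of 3122 went to 6030 and 8472 without N2 replicates 1 and 2, and to 1683 and 1725 without mutant replicates 1 and 2.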

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

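Each pattern below was chosen for a check after its result had been seen, and the predictions were written before the test was run. The interaction test of the difference between strains singled out 644 genes for diamide and ncs2Δ in footprints, 148 for rapamycin and ncs2Δ, 309 for rapamycin and elp6Δ, and 186 for diamide and ncs2Δ in mRNA.

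The rise of yolk and eggshell genes in tut-1 footprints may come from animals of a later stage. The 1250 genes at least 4-fold higher in tut-1 replicate 1 exceeded the other genes in N2 adult mRNA over N2 footprints of the fourth stage by a median log2 of 3.22, and 96.8% lay above the median of the other genes. Major sperm protein genes do not follow this reference, with a median level of 0.798 CPM in N2 adult mRNA, where yolk genes had 707 and oocyte and eggshell genes 738, so their rise is left open. The test also compares mRNA with footprints, so the assay differs too. A low N2 level at the fourth stage enters both the choice of genes and their score, so an excess could arise under other causes. Unequal depth did not account for the rise, as the median of the called list members was 5.61 after thinning and 4.92 before, with 32 of 37 members called. A difference of stage was therefore not separated from an effect of tut-1.

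The larger number of changes in ncs2Δ elp6Δ was tested against the MET17 difference. Of 3209 genes called there, 2946 (91.8%) moved the same way in ncs2Δ against the wild type without cycloheximide, where neither strain had MET17. The direction of most of these changes was thus also seen without the marker difference. As the double deletion also lacks NCS2, the test cannot tell whether the marker added to the number or size of the changes. Mixing with more than a small share of cells that carry NCS2 was excluded, as the highest NCS2 level of a double-deletion library was 0.289% of the wild-type mean. That level cannot show cells of other strains that lack NCS2.

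A lower start alone did not explain the weaker fall of ribosomal protein genes under rapamycin in ncs2Δ. These genes were higher than in the wild type under the drug (median log2 0.165, 46 higher and 1 lower of 137). They were lower in YPD (median log2 -0.161), so the start may supply part of the weaker fall. The weaker fall was not due to a single library, as the median interaction ranged from 0.264 to 0.424 with each library left out. A smaller response of all genes remained possible, with slopes of the ncs2Δ on the wild-type response of 0.886 for rising and 0.804 for falling genes. Genes chosen by their wild-type response favour slopes below 1, so the opposite slopes, of the wild-type on the ncs2Δ response for genes chosen in ncs2Δ, were added afterwards. They were 1.02 for rising and 1.18 for falling genes, which also leaves a smaller response in ncs2Δ possible, mostly for falling genes.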

How the results depend on the processing

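The alternatives were fixed before the data were examined, except those of the tEKQ strains against the wild type, which were chosen after the counts had been seen. The cause of the changes below was not tested. With the replicate number as a block, 34 of 34 counts stayed within 1.5-fold, and pairing gave 0 changed counts. RLE kept 33 of 34 counts, no filter 33 of 34, DESeq2 28 of 34 and a fit of the contrast groups only 19 of 26.

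DESeq2 called 338 genes for rapamycin and ncs2Δ (148), 487 for ncs2Δ mRNA (303), 8 for rapamycin and ncs2Δ in mRNA (0), 92 for elp6Δ efficiency (50), 23 for ncs2Δ efficiency (8) and 498 for rapamycin efficiency (219). Contrast groups alone gave 108 for cycloheximide in the wild type (427), 42 and 139 for tEKQ in elp6Δ (102) and ncs2Δ (314), 923 and 200 for mRNA of elp6Δ (462) and ncs2Δ (303), 108 for elp6Δ efficiency and 417 for that of the double deletion (672). RLE gave 114 for rapamycin efficiency, and no filter 2650 for nematode footprints (1682).

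Leaving out 1 library in turn gave, lowest to highest, 128 to 335 for ncs2Δ with tEKQ, 163 to 465 for cycloheximide in the wild type, 56 to 591 for rapamycin and elp6Δ, 25 to 428 for rapamycin and ncs2Δ, 30 to 201 for tEKQ in elp6Δ, 126 to 355 for tEKQ in ncs2Δ, 98 to 175 for diamide and ncs2Δ in mRNA, 210 to 346 for elp6Δ mRNA, 159 to 313 for ncs2Δ mRNA, 0 to 8 for rapamycin and ncs2Δ in mRNA, 12 to 63 for elp6Δ efficiency, 4 to 14 for ncs2Δ efficiency, 444 to 1005 for the double deletion's efficiency, 44 to 1104 for rapamycin efficiency, 511 to 1896 for nematode footprints and 1683 to 8472 for nematode mRNA. Diamide and ncs2Δ in footprints stayed at 471 to 625 (644). A nematode group left with 1 library was assumed to vary like the other group.

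Codon correlations weakened with AAA alone for elp6Δ with the empty plasmid (0.00862), ncs2Δ footprints (-0.0244) and double-deletion mRNA (-0.0209), with GAA alone for ncs2Δ footprints (-0.0138) and with CAA alone for ncs2Δ efficiency (-0.0155). They reversed and passed with AAA alone for ncs2Δ mRNA (0.0632) and with GAA alone for ncs2Δ efficiency (0.0473). They turned sign without passing with CAA alone for elp6Δ with the empty plasmid (-0.0140, adjusted p = 0.305) and with GAA alone for efficiency in elp6Δ (0.0110, adjusted p = 0.453) and the double deletion (0.00229, adjusted p = 0.867).

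With an estimated correlation 195 of 247 list calls were lost. With a library left out, 1734 of 1878 list calls stayed, 141 were lost with the direction of camera kept and 3 with that direction turned but not passing, and 3 lists without a call before were called in the opposite direction. The 3 lost with a turned direction were the ribosomal proteins in the cycloheximide interaction (0.0124 with adjusted p = 0.774 without wild-type YPD replicate 3, -0.0890 without wild-type replicate 2 made without the drug), ribosome biogenesis for tEKQ in ncs2Δ (-0.0117, adjusted p = 0.748, and 0.153 without empty plasmid replicates 3 and 1) and the Msn2 and Msn4 genes for rapamycin and ncs2Δ in mRNA (0.243 and -0.0557, the latter with adjusted p = 0.68, without wild-type rapamycin replicates 3 and 2). The lists without a call before were the Msn2 and Msn4 genes for rapamycin and elp6Δ (-0.129 and 0.199 without elp6Δ rapamycin replicates 3 and 2) and, for rapamycin and ncs2Δ in mRNA, the Gcn4 targets (0.119 and -0.111) and glycolysis (0.183 and -0.173) without wild-type rapamycin replicates 3 and 2. Gene calls were followed for the genes picked for naming only, counted once per library left out. Of 10322 such calls 9331 stayed, 991 were lost and 0 reversed. Genes named by size were chosen for large changes, which made reversals unlikely.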

Other observations

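The test of the phosphate genes was chosen after the falls of PHO84, SPL2, PHO5 and VTC3 had been seen, and the split tests below after the counts. Other members of the phosphate regulon (PHO11, PHO89, PHO8, PHO81, PHM6, PHM8, VTC1, VTC4 and GIT1) had a median log2 of -1.83 in double-deletion footprints, with 8 of 9 lower and 1 higher. The words that these members share with other genes are not given here, so single members may be uncertain. The median of the members was -0.84 in ncs2Δ, -0.51 in elp6Δ, -0.88 in ncs2Δ without cycloheximide and -1.15 in double-deletion mRNA. With empty plasmids in selective medium it was 0.24 in ncs2Δ (3 higher, 1 lower) and 0.31 in elp6Δ (2 higher, 1 lower), for the 7 members measured. PHO84, which is not among these members, fell in both mutants there too, so the regulon did not move as one in that medium. A hypothesis is that these strains sense phosphate as more abundant in YPD, which may lower the Pho4 regulon. Phosphate uptake and Pho4 localisation in ncs2Δ, elp6Δ and the double deletion, with and without MET17, would test it.

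The libraries of each comparison were regrouped, and the test was repeated. For 3 libraries against 3 there are 10 splits, never a share under 0.1. In each of these the real split (1 of 10) had the most calls. Real counts and the highest of the other splits were 1776 and 1 for ncs2Δ footprints, 2189 and 0 for elp6Δ, 3234 and 0 for the double deletion, 303 and 0, 462 and 0, and 1823 and 0 for their mRNA, 4357 and 0 for diamide footprints in the wild type, 4481 and 0 in ncs2Δ, 3729 and 0, 3466 and 0, and 3500 and 0 for rapamycin in the wild type, ncs2Δ and elp6Δ, 4031 and 0 for diamide mRNA and 3114 and 0 for rapamycin mRNA. They were 1579 and 0 for ncs2Δ and 1980 and 0 for elp6Δ with the empty plasmid, 314 and 1 for tEKQ in ncs2Δ, 102 and 8 in elp6Δ, 307 and 0 for ncs2Δ with tEKQ and 1502 and 0 for elp6Δ with tEKQ against the wild type, 1686 and 0 for ncs2Δ without cycloheximide, and 427 and 0 for the drug in the wild type.

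For interactions and efficiency 100 of 200 splits were drawn, and chance was not excluded where genes were called. As many calls as the real count came from 17 splits for ncs2Δ efficiency (8, highest other 836), 16 for elp6Δ (50, 965), 14 for the double deletion (672, 2164), 9 for diamide (922, 2609) and 6 for rapamycin (219, 1480). For the interactions they came from 5 splits for diamide and ncs2Δ in footprints (644, 1102) and 5 in mRNA (186, 651), 14 for rapamycin and ncs2Δ (148, 1155) and 14 for rapamycin and elp6Δ (309, 1213). For rapamycin and ncs2Δ in mRNA (0, 1) and for cycloheximide and ncs2Δ (0, 546) the real count was 0, so all 100 splits matched it by definition and these do not bear on chance. Splits with several times the real count point to structure of the samples, as a split that moves libraries of a treatment unevenly carries the common effect into the contrast. A view restricted to the 44 balanced splits was chosen after these results had been seen. There the real split alone had as many calls for each result with any call, and the highest other counts were 2 for ncs2Δ efficiency, 4 for rapamycin and ncs2Δ and 0 elsewhere. Each other balanced split puts libraries of both exchanged groups into the same group, so their common difference enters the spread. Few calls were thus likely there with or without an interaction, and these splits do not bear on chance.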
